A study of Mus musculus with 23 samples.

How the data were processed

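Gene expression was measured on whole-transcript microarrays in the nucleus accumbens, a ventral part of the striatum, of 23 C57BL/6 mice, with 1 array per mouse. Per the labels, the tissue was micropunched at an age of about 15 weeks, about 5 weeks after an adeno-associated virus (AAV) carrying either a short hairpin RNA against Nr1d1 or a scrambled control hairpin had been injected into the region. Nr1d1 encodes REV-ERBα, a nuclear receptor of the circadian clock that represses transcription. The groups were 5 control and 6 knockdown females and 6 control and 6 knockdown males, and the series describes all samples as biological replicates. The labels' treatment text also speaks of a postpartum day of collection, and does so for the male samples too, so the reproductive state of the females was not used here. The hour of collection is not given in the sources used here.

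Per the labels' protocols, total RNA was extracted with a kit for fatty and fibrous tissue, and cDNA for the arrays was made from 150 ng of it with a whole-transcript labelling kit. The deposited values are log2 intensities per probe set, in a single table of 41345 probe sets and 23 arrays. Per the submitters' processing notes, the authors used Transcriptome Analysis Console. Its version, the summarisation and normalization method and the genome build are not given in the sources used here. The values themselves show a normalization within each sex. The medians of the 11 female arrays lay between 6.11 and 6.17 and those of the 12 male arrays between 5.84 and 5.88, with upper quartiles of 7.76 to 7.80 and 7.49 to 7.54. The female and male arrays therefore look as if they had been normalized in separate runs, and sex and processing run cannot be told apart in a comparison of levels between males and females. A constant offset between the runs cancels in every comparison of knockdown with control. The number of arrays limits the precision, and the scanner files and a measure of signal over background were not used here.

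Probe sets were named through the annotation table of the array. It gave 1 gene symbol for 23521 probe sets, several for 1814 and none for 16010, which are unnamed here. Of the single symbols, 23328 were matched by their Entrez number to the GRCm38.p6 gene table, and the match changed 0 of them. Genes are named only from probe sets with 1 symbol, each by the probe set with the highest mean over all 23 arrays, which gave 22180 genes. Of these, 1082 had more than 1 probe set. No table marked control probe sets, so all 41345 were tested. The 5333 probe sets numbered below the first named one, among which controls would be sought, were left out in an alternative. The values of 1395 probe sets were identical to those of another probe set on every array.

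All 23 arrays entered a single linear model with 1 mean per group, fitted with limma 3.58.1 in R 4.3.3 with its default empirical Bayes settings. The model left 19 residual degrees of freedom, and the prior added 3.24. Contrasts were knockdown against control in females, the same in males, the average of both, the difference of the male and female knockdown effects, and males against females. Tests were two-sided. The Benjamini-Hochberg adjustment ran over all probe sets, with a threshold of 0.05. Errors of log2 differences of genes are standard errors (SE) from the model, and intervals are 95% confidence intervals. The SE of a difference of list means was instead taken from the spread of the list means between mice within each group. Nr1d1 and the list means were also compared within each sex by a two-sided exact permutation test, which can reach p = 0.00216 in either sex. The p values of limma and of the permutation test rest on the spread between the mice of a group.

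The analysis design, 20 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 331 genes, of which 301 had a probe set of their own. They cover the circadian clock, genes that REV-ERB represses, striatal neurons, receptors, early genes, glial, vascular and ependymal cells, cortical excitatory neurons (as a marker of neighbouring tissue), lymphocytes, interferon, p53 and endoplasmic reticulum stress responses, and sex chromosome genes. Each list was tested with camera at a preset correlation of 0.01 over the 22180 genes, then with camera at an estimated correlation and with fry, with the adjustment over the 20 lists of a contrast. The preset value treats the genes of a list as nearly independent. Where they move together, p values at it do not measure the spread between mice. The estimated correlation was 0.585 for medium spiny neuron, 0.316 for interferon and 0.194 for microglial genes. For lymphocyte genes it was 0.092, for REV-ERB repressed targets 0.048 and for clock genes 0.031. The named genes are Nr1d1, the genes past the threshold, the 5 genes with the smallest unadjusted p where fewer than 5 passed, and for each list the members past the threshold or else the 2 members with the smallest p. For males against females the rule takes the sex chromosome genes and the 5 largest rises and falls outside them. The text gives a subset of these.

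The model was tested on simulated data with the real levels and spreads. At changes of 0.25, 0.5 and 1 on the log2 scale, 41%, 91.5% and 99.5% of 200 changed probe sets each were recovered among 41345 in the female contrast. In the male contrast the shares were 46%, 94% and 100%. False calls were 23 of 487 in females and 31 of 511 in males. These data held many changed probe sets, and fewer would be recovered where few change. Each simulated probe set was drawn independently, so genes did not move together in them.

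Alternatives were an intensity trend with robust variance, quantile normalization over all arrays, array weights, a filter at the 30th percentile of level, 1 named probe set per gene, each sex fitted alone, the replicate number as a block, the means of the medium spiny neuron and cortical lists as covariates, leaving out each array in turn, and a threshold of 0.10. Chosen after the data had been seen were the omission of female knockdown arrays 3 and 4, which had the largest residual spread, the omission of male control arrays 1 and 6, which had the lowest means of the lists called in males, the omission of the low-numbered unnamed probe sets, and leaving out each array in turn for the gene lists. Leaving out the lowest controls of a list must shrink a rise of that list. The omission of male control arrays 1 and 6 therefore cannot test the lists called in males. No pair of arrays had identical values, and the highest correlation between arrays was 0.994. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome coordinates are given, as the files name no build.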

Results

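Microarray profiles of the nucleus accumbens, a brain region of reward and social motivation, were compared between mice injected there with AAV carrying a hairpin against Nr1d1 and mice given a scrambled hairpin, in females (5 control and 6 knockdown) and in males (6 and 6). The series asks how this circadian gene in the region bears on social reward and anxiety-related behaviour, and the arrays address which transcripts differ after its knockdown in each sex. Values are the deposited log2 intensities, and n is the number of mice.

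The targeted transcript was measured first. Nr1d1 (probe set 17268884) stood at 10.04 ± 0.07 (SD, n = 5) in control females and 9.99 ± 0.16 (SD, n = 6) in females labelled knockdown. The difference was −0.05 on the log2 scale (SE 0.09, 95% interval −0.24 to 0.13), smaller than the spread between mice by the exact permutation test (p = 0.563) and by limma (adjusted p = 0.963). In males it stood at 9.59 ± 0.20 (SD, n = 6) in controls and 9.58 ± 0.13 (SD, n = 6) in the arrays labelled knockdown, a difference of −0.01 (SE 0.09, interval −0.19 to 0.17, exact permutation p = 0.926). It lay below the control mean in 4 of 6 females and 3 of 6 males labelled knockdown. The lower bounds of the intervals correspond to changes of −15.2% in females and −12.3% in males. Only 1 probe set measured Nr1d1, and it can also read RNA fragments left by cleavage. Since no fall of Nr1d1 RNA was detectable, the groups are called arrays labelled knockdown here, and every direction below rests on that label.

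**Figure D1:**
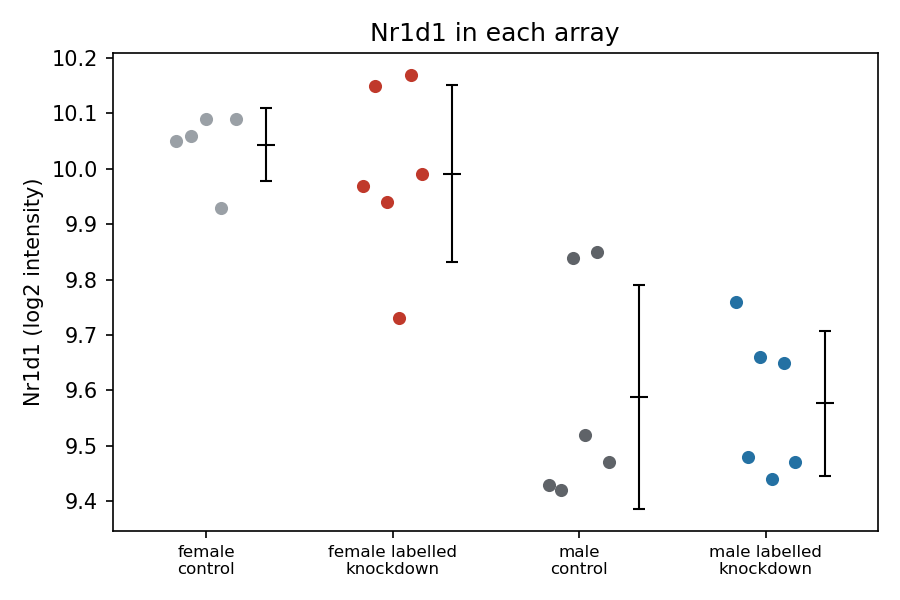
Nr1d1 log2 intensity (vertical axis) in each of the 23 arrays by group; points are mice, and the bar beside them gives the mean and SD. Levels ranged from 9.73 to 10.17 in females and from 9.42 to 9.85 in males, and the arrays labelled knockdown overlapped the controls in both sexes.

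In females, no gene passed the threshold, and the gene groups called at the preset correlation, both by small amounts, were genes that REV-ERB represses and lymphocyte genes. Of 9 measured REV-ERB repressed targets, 8 were higher in the arrays labelled knockdown, with a mean difference of 0.09 (camera adjusted p = 0.0107). The call did not hold with an estimated correlation (adjusted p = 0.171). Members with the smallest p were Nfil3, a repressor of clock-controlled genes, at 0.17 (SE 0.06), and Ccl2, a chemokine, at 0.15 (SE 0.07). All 14 measured T and B lymphocyte genes were higher, by 0.09 on average (camera adjusted p = 0.0107), a call that did not hold with an estimated correlation either (adjusted p = 0.30). Among them were the chemokine gene Ccl5 at 0.19 (SE 0.10) and Cd3d, a part of the T cell receptor complex, at 0.13 (SE 0.07). The list was of low level, with a mean of 5.49 over all arrays. In control females Ccl5 stood at 6.00 and Cd3d at 4.80, the latter near the lower quartiles of 4.77 to 4.79 of these arrays. The median of all genes of the lymphocyte genes' level was itself higher by 0.03, against a list median of 0.11. Without female knockdown replicate 4 neither call remained (camera adjusted p = 0.179 and 0.20), the REV-ERB difference being 0.07 and the lymphocyte difference 0.06. The lymphocyte call was also lost after quantile normalization (camera adjusted p = 0.0649). Per mouse, the mean of the REV-ERB list was 8.18 ± 0.07 (SD, n = 6) against 8.09 ± 0.02 (SD, n = 5; exact permutation p = 0.0108, adjusted over the 20 lists 0.217). That of the lymphocyte list was 5.68 ± 0.10 (SD, n = 6) against 5.58 ± 0.05 (SD, n = 5; exact permutation p = 0.0736, adjusted 0.491).

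By limma, 0 of 41345 probe sets passed the adjusted threshold in females, also at 0.10, with a lowest adjusted p of 0.251. At an unadjusted p under 0.05 there were 2423, of which 1386 were higher, where uniform p values would give 2067.25. Other assignments of the females to the groups gave 1053 to 3490, with a median of 1634. The genes with the smallest p were Smim26 at −0.27 (SE 0.06), Zbtb42 at 0.25 (SE 0.06), Tinf2, a component of the telomere-protecting shelterin complex, at −0.23 (SE 0.05), Mageb4 at 0.25 (SE 0.06) and Prpf19, a splicing factor, at −0.18 (SE 0.04). Each lay on the same side of the control mean in 6 of 6 mice, and their adjusted p lay between 0.732 and 0.817. The 95% interval reached 0.17 to either side of the difference in the median probe set. That interval is not adjusted for the number of probe sets tested. In simulated data with many changed probe sets, 41% of changes of 0.25 were recovered in this contrast. That share overstates what could be found in these females if few genes changed.

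The remaining lists gave no call in females. Of the 19 measured clock genes 12 were higher (adjusted p = 0.291), with the clock output factor Hlf at 0.11 (SE 0.05). Per mouse, the clock list mean was 9.19 ± 0.03 (SD, n = 6) against 9.16 ± 0.01 (SD, n = 5). Its exact permutation p was 0.0303, and 0.303 adjusted over the 20 lists. Medium spiny neuron genes, which mark the main cell type of the region, were 12 higher and 10 lower (adjusted p = 0.920), with the transcription factor gene Foxp1 at 0.11 (SE 0.09). Interneuron genes were lower in 10 of 13 (adjusted p = 0.189), with the receptor kinase gene Kit at −0.14 (SE 0.07). Among the 30 measured GABA and glutamate receptor genes 21 were lower (adjusted p = 0.734), while Gabra2, a GABA-A receptor subunit, stood at 0.18 (SE 0.07). Among 28 neuropeptide and hormone receptor genes 18 were lower (adjusted p = 0.734), with the progesterone receptor Pgr at −0.16 (SE 0.07). Activity-dependent early genes were higher in 16 of 21 (adjusted p = 0.0999), with Nr4a3 at 0.42 (SE 0.24) and Egr2 at 0.23 (SE 0.16). Astrocyte genes were lower in 10 of 14 (adjusted p = 0.189), with S100b at −0.17 (SE 0.07), and microglial genes in 11 of 18 (adjusted p = 0.734), with Tmem119 at −0.09 (SE 0.05) and Trem2 at −0.11 (SE 0.06). Interferon response genes were higher in 17 of 21 (adjusted p = 0.0640), with the immunoproteasome subunit Psmb8 at 0.17 (SE 0.10), and without female knockdown replicate 4 their mean difference went from 0.09 to 0.003. For the other 9 lists the adjusted p was 0.595 or more.

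In males, the groups called at the preset correlation were medium spiny neuron and microglial genes, again by small amounts and with no single gene past the threshold. Of 22 measured medium spiny neuron genes, 21 were higher in the arrays labelled knockdown, by 0.09 on average (camera adjusted p = 2.59e-05), a call that did not hold with an estimated correlation (adjusted p = 0.534). The difference fell to 0.05 without male control replicate 1, to 0.06 without male control replicate 6 and to −0.002 without both (camera adjusted p = 0.997), whose list means of 9.90 and 9.93 lay below the 10.15 to 10.22 of the other 4 controls. Examples were Bcl11b, a transcription factor of these neurons, at 0.13 (SE 0.07), and Tac1, the substance P precursor of the direct pathway, at 0.11 (SE 0.06). Of 18 microglial genes 17 were higher, by 0.07 on average (camera adjusted p = 5.04e-05), which did not hold with an estimated correlation (adjusted p = 0.513). The same 2 controls were the lowest here as well, at 7.38 and 7.36 against 7.45 to 7.55 in the other 4, and without both the difference was 0.04 (camera adjusted p = 0.107). As these 2 controls had been chosen for low means of these 2 lists, a smaller difference without them was bound to follow. Both calls stayed in all 23 leave-one-out runs at the preset correlation. Camera adjusted p reached 0.0221 for medium spiny neuron genes and 0.00594 for microglial genes. Only the runs without 1 of the 12 male arrays could change either difference. All of these p values carry the limit of the preset correlation. Microglial members included Siglech at 0.13 (SE 0.05) and the lipid-sensing receptor gene Trem2 at 0.15 (SE 0.06). Cortical excitatory neuron genes, markers of tissue outside the accumbens, varied widely between the male mice, with list means of 6.82 ± 0.81 (SD, n = 6) in controls and 7.13 ± 0.52 (SD, n = 6) in the arrays labelled knockdown (exact permutation p = 0.424). Per mouse, the microglial list mean was 7.52 ± 0.03 (SD, n = 6) against 7.45 ± 0.07 (SD, n = 6; exact permutation p = 0.0368, adjusted 0.736), and for the medium spiny neuron list the exact permutation p was 0.229.

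By limma, 0 of 41345 probe sets passed in males, also at 0.10, with a lowest adjusted p of 0.10. At an unadjusted p under 0.05 there were 1948, of which 912 were higher, where uniform p values would give 2067.25. Other assignments of the males to the groups gave 1613 to 4477, with a median of 2292. The smallest p values among genes were those of the small nucleolar RNAs Snord37 at −0.63 (SE 0.14) and Snora20 at 0.39 (SE 0.09), the transporter gene Slc17a4 at 0.31 (SE 0.07), the follicle-stimulating hormone subunit Fshb at −0.26 (SE 0.06) and Lage3 at 0.26 (SE 0.06). Each lay on the same side of the control mean in 6 of 6 mice, with adjusted p from 0.767 to 0.822. C1ql1, in the oligodendrocyte precursor list, was higher by 0.23 (SE 0.07) in 6 of 6 mice. It was the 1 gene that passed when adjusted over the list alone (adjusted p = 0.0256), against an adjusted p of 0.996 over all probe sets.

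Other lists gave no call in males. Clock genes were higher in 14 of 19 (adjusted p = 0.109), with Per1, a core repressor of the clock, at 0.17 (SE 0.07) in 6 of 6 mice and Ciart at 0.17 (SE 0.08). REV-ERB repressed targets were higher in 5 of 9 (adjusted p = 0.907), with Fabp7, a lipid-binding protein of astrocytes, at 0.20 (SE 0.11) and Ccl2 at −0.16 (SE 0.07). Myelin genes were lower in 11 of 16 (adjusted p = 0.109), with Aspa at −0.27 (SE 0.11). Among the 28 neuropeptide and hormone receptor genes (adjusted p = 0.884) the serotonin receptor Htr1a stood at −0.27 (SE 0.11) and the peptide gene Cartpt at 0.24 (SE 0.10). Interneuron genes were 6 higher and 7 lower (adjusted p = 0.907), with Nos1, the neuronal nitric oxide synthase, at 0.15 (SE 0.06). Ependymal genes were higher in 8 of 10 (adjusted p = 0.142), with the ciliogenesis factor Foxj1 at 0.15 (SE 0.07). Cortical genes were higher in 8 of 9 (adjusted p = 0.164), with the vesicular glutamate transporter Slc17a7 at 1.17 (SE 0.85), the largest difference among the named genes of this contrast. For the remaining lists the adjusted p was 0.164 or more.

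**Figure D2:**
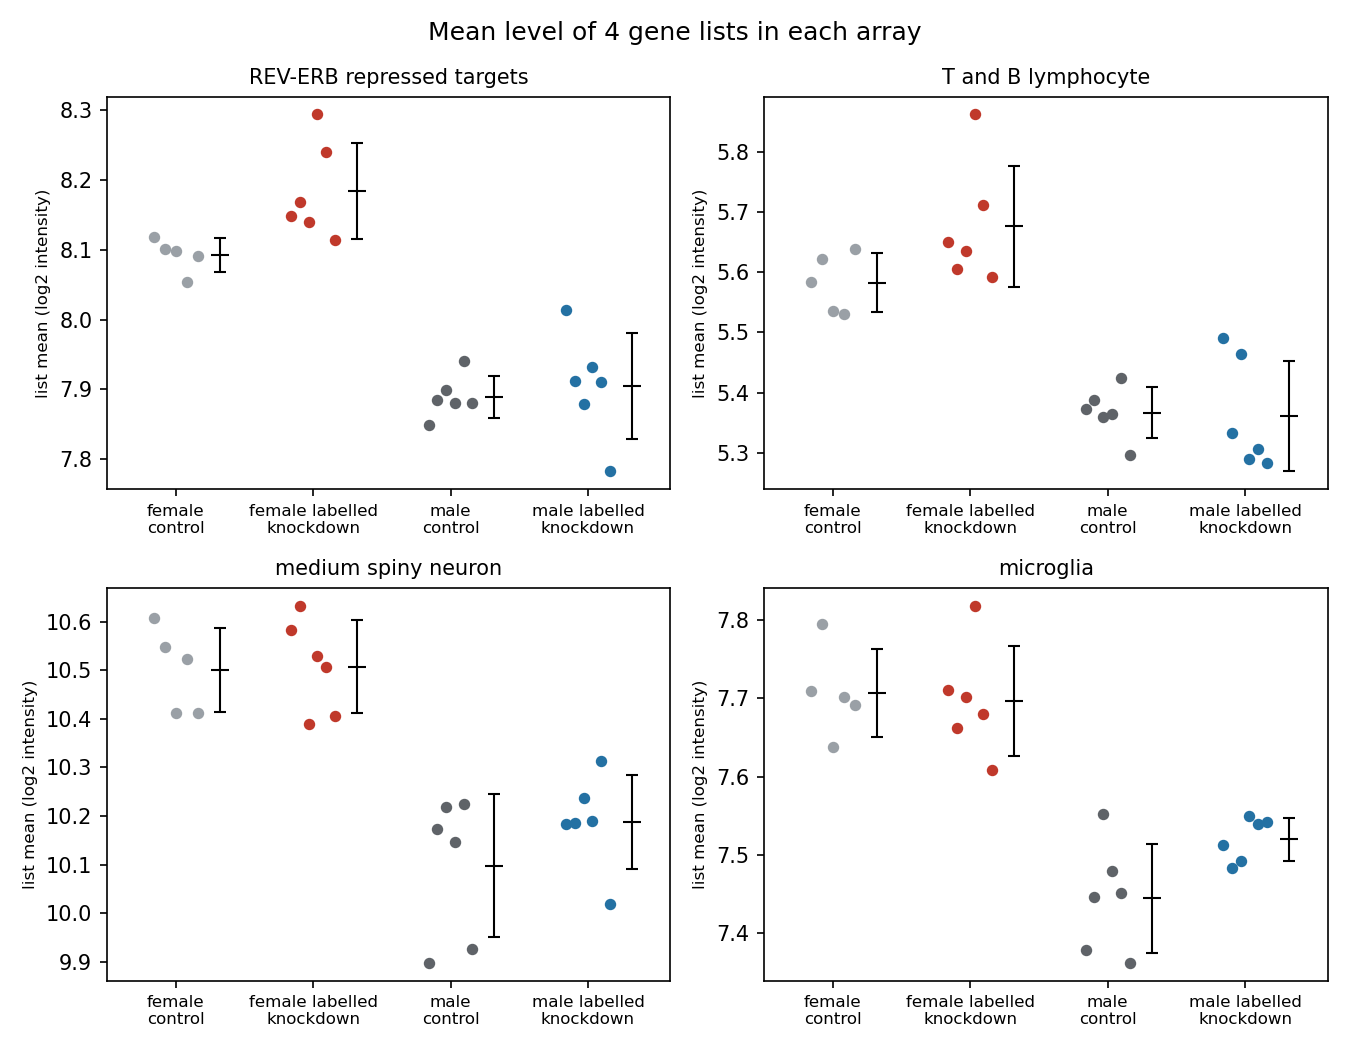
Mean log2 intensity of 4 gene lists (vertical axes) in each array by group; points are mice, and bars give the mean and SD. The 6 females labelled knockdown have a mean of 8.18 for the REV-ERB repressed targets against 8.09 in controls, and for every list the groups overlap.

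Averaged over both sexes, clock genes, REV-ERB repressed targets and medium spiny neuron genes were higher as groups in the arrays labelled knockdown at the preset correlation. With an estimated correlation no call held, at adjusted p = 0.266 for the clock genes, 0.266 for the REV-ERB targets and 0.725 for the medium spiny neuron genes. The clock and REV-ERB lists are not independent, as 5 of the 9 measured REV-ERB targets (Arntl, Clock, Npas2, Cry1 and Nfil3) are also clock list members. Clock genes were higher in 16 of 19, by 0.04 on average (camera adjusted p = 0.0417), with Per1 at 0.14 (SE 0.05) in 12 of 12 mice. The REV-ERB targets were higher in 7 of 9, by 0.05 (camera adjusted p = 0.0436), with the activator gene Npas2 at 0.14 (SE 0.07) and Fabp7 at 0.18 (SE 0.08). Rora, a nuclear receptor that activates the sites REV-ERB represses, stood at −0.09 (SE 0.04), on the same side in 12 of 12 mice. Medium spiny neuron genes were higher in 21 of 22, by 0.05 (camera adjusted p = 0.0112), with Gpr6 at 0.11 (SE 0.07) and Syndig1l at 0.11 (SE 0.07), and their mean difference was 0.03 without either of male control replicates 1 and 6 and 0.003 without both. The clock call ended when any of 8 single arrays was left out, the REV-ERB call with any of 11 and the medium spiny neuron call with any of 7, with adjusted p up to 0.114, 0.123 and 0.121. In these single-array runs the difference stayed between 0.033 and 0.046 for clock genes and between 0.043 and 0.066 for REV-ERB targets. All 3 calls ended without male control replicates 1 and 6 together (adjusted p = 0.0893, 0.0893 and 0.951). As these 2 controls had been chosen for low means of the medium spiny neuron and microglial lists, a smaller medium spiny neuron difference was bound to follow. Microglial genes were higher in 14 of 18 (adjusted p = 0.0565), with Laptm5 at 0.10 (SE 0.05).

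By limma, 0 probe sets passed in the average, also at 0.10, and 1949 had an unadjusted p under 0.05. The 5 genes with the smallest p were Dennd1c at 0.30 (SE 0.06), Speer4d at −0.23 (SE 0.05), Actl11 at −0.20 (SE 0.05), Gtpbp3, which modifies mitochondrial tRNA, at 0.18 (SE 0.04) and the salt-inducible kinase Sik2 at 0.15 (SE 0.04), with adjusted p of 0.925 to 0.980. Except for Actl11, with 11 of 12, each lay on the same side of its control mean in 12 of 12 mice. List members on the same side in at least 10 of 12 mice included Kit at −0.12 (SE 0.05), Gabra2 at 0.12 (SE 0.05), Pgr at −0.11 (SE 0.05), Aspa at −0.19 (SE 0.08), C1ql1 at 0.15 (SE 0.05) and the T cell gene Cd8b1 at 0.13 (SE 0.05), none past the threshold. The other 16 lists had adjusted p of 0.107 or more.

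The difference of the knockdown effect between the sexes was tested directly. Relative to females, the male difference was higher for medium spiny neuron genes (19 of 22 members, by 0.08 on average, camera adjusted p = 0.0194, and adjusted p = 0.849 with an estimated correlation) and for microglial genes (14 of 18, by 0.09, camera adjusted p = 0.00811, and 0.456 with an estimated correlation). It was lower for lymphocyte genes (11 of 14, by −0.10, camera adjusted p = 0.0327, and 0.456 with an estimated correlation) and interferon response genes (16 of 21, by −0.14, camera adjusted p = 0.0194, and 0.809 with an estimated correlation), so no call held with an estimated correlation. The interferon difference was −0.06 without female knockdown replicate 4 and −0.09 without male control replicate 1, the lymphocyte difference −0.06 without female knockdown replicate 4, and the medium spiny neuron difference 0.04 and 0.05 without male control replicate 1 and replicate 6. Without both of these the latter was −0.009 (camera adjusted p = 0.926) and the microglial difference 0.05 (0.189), and the lymphocyte and interferon calls ended as well (0.0596 and 0.189). The lymphocyte call was also lost in 11 of 23 leave-one-out runs, the medium spiny neuron call in 7 and the interferon call in 4, with adjusted p up to 0.209, 0.228 and 0.413. After quantile normalization these 3 calls ended (adjusted p = 0.140, 0.140 and 0.0526), as they did with array weights (0.0528, 0.0967 and 0.0528). By fry, which tests whether a list moves on balance in 1 direction, the count of calls was 0 of 20 lists in each of the knockdown contrasts. The microglial members with the smallest p were Trem2, with a difference of 0.26 (SE 0.09), and the complement gene C1qa at 0.22 (SE 0.10). For the other lists these were Tac1 at 0.17 (SE 0.09) and the phosphodiesterase gene Pde1b at 0.17 (SE 0.11), Cd3d at −0.20 (SE 0.10) and the B cell receptor gene Cd79b at −0.23 (SE 0.11), and the antiviral genes Mx2 at −0.40 (SE 0.18) and Usp18 at −0.36 (SE 0.21). Among the REV-ERB targets, lower in 7 of 9 (adjusted p = 0.0885), Ccl2 differed by −0.31 (SE 0.10) and was the 1 gene past the threshold adjusted over the list alone (adjusted p = 0.0439, against 0.845 over all probe sets). Nfil3 stood at −0.20 (SE 0.09), Ciart at 0.27 (SE 0.11) and Cartpt at 0.32 (SE 0.15).

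By limma, 0 probe sets passed for this difference, also at 0.10, and 2358 had an unadjusted p under 0.05. With array weights 1 probe set passed. The genes with the smallest p were Snora20 at 0.63 (SE 0.13), the spliceosomal protein gene Snrpd1 at 0.46 (SE 0.10), Gm11793 at −0.39 (SE 0.09), Gm10847 at −0.38 (SE 0.09) and Znrd1, a subunit of RNA polymerase I, at 0.36 (SE 0.09), with adjusted p from 0.376 to 0.845. A second probe set of Snrpd1 gave 0.21. Across all 41345 probe sets the female and male log2 differences were uncorrelated, with Pearson r = −0.02 and Spearman rho = −0.02. These are correlations across probe sets, which are not independent replicates, and other assignments of the mice to groups gave Pearson values between −0.16 and 0.18. Of the probe sets with an unadjusted p under 0.05 in each sex, 137 were shared, 57 of them with the same sign, where independent lists would share 114.

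Males and females differed first by the genes of the sex chromosomes. Xist, the RNA that silences an X chromosome, was lower in males by −7.60, and the Y-linked genes Eif2s3y, Uty and Kdm5d were higher by 4.64, 4.42 and 3.64. As females carry no Y chromosome, their group means of 3.72 to 4.10 for these genes are background signal, and Xist stood at 3.98 and 3.99 in the male groups, so background limits the size of these 4 differences. The X-linked genes Ddx3x, Kdm6a and Kdm5c, which escape X inactivation, were lower in males by −0.71 (SE 0.05), −0.68 (SE 0.04) and −0.51 (SE 0.05). The median probe set was −0.27 lower in males as deposited, and after quantile normalization over all arrays these 3 genes stood at −0.46, −0.42 and −0.25. Outside this list the largest rises in males were Fam25c at 1.60 (SE 0.07), Clec5a at 0.74 (SE 0.06), Cmah at 0.73 (SE 0.05), Rpl15-ps6 at 0.72 (SE 0.06) and Tssk2 at 0.69 (SE 0.04). The largest falls were Slc17a7 at −2.29 (SE 0.62), the neuritin gene Nrn1 at −1.53 (SE 0.35), Olfr111 at −1.41 (SE 0.13), Gm12770 at −1.32 (SE 0.06) and the synaptic zinc transporter Slc30a3 at −1.27 (SE 0.28), and all of these genes passed the threshold (limma adjusted p of 0.00197 or less). Slc17a7 and Slc30a3 belong to the cortical list, whose mean was 7.74 and 7.75 in the female groups and 6.82 and 7.13 in the male groups. With the medium spiny neuron and cortical list means as covariates, Slc17a7 was higher in males by 0.79. The cortical mean holds Slc17a7 itself, and both means were lower in males. The covariates thus take up part of the sex difference, and this value is no estimate of it.

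**Figure D3:**
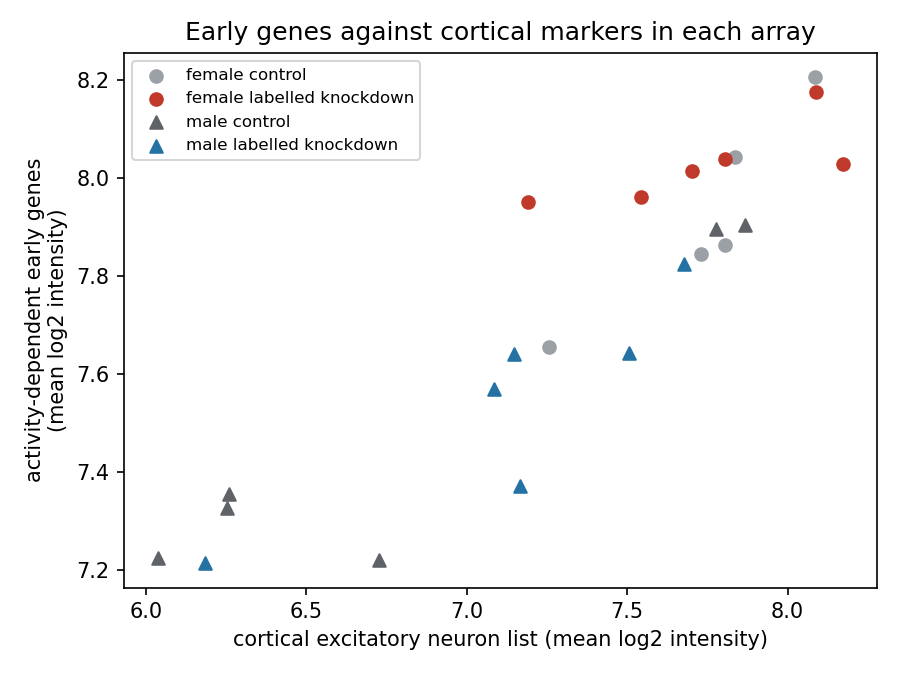
Mean log2 intensity of the activity-dependent early genes (vertical axis) against that of the cortical excitatory neuron genes (horizontal axis), with 1 point per mouse, circles for females and triangles for males. The cortical mean ranged from 7.19 to 8.17 in females and from 6.04 to 7.87 in males, and mice with a higher cortical mean had higher early genes.

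In all, 31736 of 41345 probe sets passed between males and females, 1286 higher and 30450 lower in males. After quantile normalization 17496 passed, 8724 higher and 8772 lower, so the share of higher calls moved from 4.05% to 49.9%. As the arrays of each sex look normalized apart from each other, sex and processing run cannot be told apart in these values.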

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

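The tests of the shift of all genes of a level, of exchanged samples, of the probe set, of dilution and of deviating arrays were chosen after the results were seen, and what the counts of other splits would show was written down only after these counts were known.

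The absence of a detectable fall of Nr1d1 in the arrays labelled knockdown was weighed first. Samples exchanged between the groups would leave levels at least 1 log2 unit apart within a sex if the knockdown lowered the level by 1 log2 unit or more, and so would correct labels. The larger of the within-sex ranges was 0.44, so no array stood that far below the others of its sex. This argues against an exchange that hid a fall of that size. An exchange under a smaller or absent fall cannot be seen by this test. A probe set blind to Nr1d1 RNA stays open: after removal of group means and the cortical score its correlation with Dbp, another clock-controlled transcript, was 0.577 over 23 arrays, but 0.21 in females and 0.78 in males, and before removal of the score Npas2, Cry1 and Ciart moved with the probe set (r of 0.67, −0.59 and 0.56) while Nr1d2, Tef and Per3 did not (−0.22, −0.26 and 0.04). Dilution by cells that the virus did not reach cannot be told apart from a hairpin without effect on the RNA, because no probe set is known here to measure the vector, and the interval in females allows a change of up to −15.2%. A biological explanation, such as a fall of REV-ERBα protein without one of its RNA, was not tested.

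The higher values of REV-ERB repressed targets and lymphocyte genes in females labelled knockdown, called at the preset correlation but not with an estimated one (adjusted p = 0.171 and 0.30), were weighed next. The median of all genes of the REV-ERB targets' level was −0.009, so a shift of that level did not point upwards. The list median lay 0.09 above it (exact permutation p = 0.0476, not adjusted for the 2 lists). For the lymphocyte genes, whose median lay 0.08 above that of their level (exact permutation p = 0.0714), such a shift cannot be told apart from a rise of the list. Both lists were taken up because they had been called in these same arrays, so neither p is independent support for a rise. Without female knockdown replicate 4 the lymphocyte difference fell from 0.09 (SE 0.05) to 0.06 (SE 0.03) and its adjusted p became 0.20, while without any other female array it was 0.0410 or less, so this call may rest on that array, whose list mean was 5.86 against 5.59 to 5.71 in the other 5. For the REV-ERB targets the difference went from 0.09 (SE 0.03) to 0.07 (SE 0.02) and the adjusted p to 0.179, against 0.0374 or less without any other female array. This part cannot be told apart from a smaller difference shared by the mice, since the difference kept most of its size while the call ended, and an effect of the hairpin stays open as well.

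Female knockdown replicate 4 also stood above the other 5 females labelled knockdown in interferon (6.71 against 6.10 to 6.34), reactive astrocyte (6.74 against 6.30 to 6.50), endothelial (8.23 against 7.90 to 8.04), microglial (7.82 against 7.61 to 7.71), astrocyte (9.42 against 9.28 to 9.34), oligodendrocyte precursor (7.81 against 7.65 to 7.73) and p53 response genes (7.64 against 7.58 to 7.62). It stood below them in myelin genes (9.34 against 9.45 to 9.59), ependymal genes (6.125 against 6.159 to 6.327) and Nr1d1 (9.73 against 9.94 to 10.17).

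Gene lists whose knockdown effect differed between the sexes in the test of the difference itself were those of medium spiny neurons (adjusted p = 0.0194), microglia (adjusted p = 0.00811), T and B lymphocytes (adjusted p = 0.0327) and the interferon response (adjusted p = 0.0194), all with camera at its preset correlation and none with an estimated correlation. None was called without male control replicates 1 and 6 either. Those 2 controls had been chosen for low medium spiny neuron and microglial means, so for these 2 lists a smaller difference was bound to follow. The microglial call stayed in all 23 leave-one-out runs (camera adjusted p up to 0.0350).

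Samples far from the others of their group, by the ratio of their gap to the range of the group, were found in 3 of 92 tests, and chance gives about 1 in 20. Nr1d1 in female control replicate 4 was 9.93, against 10.05 to 10.09 in the other controls. The reactive astrocyte list mean in male knockdown replicate 1 was 6.395, against 6.097 to 6.165 in the others. The interferon response list mean in male control replicate 1 was 6.143, against 5.767 to 5.850 in the others.

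Chance could not be excluded for the number of probe sets at an unadjusted p under 0.05 in any knockdown contrast. Of 100 assignments of the mice to groups within each sex, the real one included, 5 gave as many as the 2423 of females (highest other 3490), 76 as many as the 1948 of males (highest other 4477), 43 as many as the 1949 of the average (highest other 4995) and 18 as many as the 2358 of the difference between the sexes (highest other 3718). For males against females chance was excluded, as among 100 divisions of all 23 mice into groups of the sizes of the sexes only 1, the real one, gave 31736 probe sets and the highest other gave 12016. The array medians of the sexes did not overlap, so the real division was bound to give many calls. This test cannot tell sex from processing run.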

How the results depend on the processing

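Chosen after the data had been seen were the omission of female knockdown arrays 3 and 4, that of male control arrays 1 and 6, that of the low-numbered unnamed probe sets, and leave-one-out runs for the gene lists. The count of probe sets past the threshold was 0 in 33 of 35 alternatives in females, 32 of 35 in males, 34 of 34 in the average and 30 of 34 in the difference between the sexes. It was 1 with array weights in the difference, 1 without male control arrays 1 and 6 in males and in the difference, and it ranged from 0 to 1 in leave-one-out runs in females (1 without female knockdown replicate 1 or male knockdown replicate 4), in males and in the difference (1 without male control replicate 1 or 5 in each). The cause was not tested. Between males and females it was 17496 after quantile normalization, 18542 with 1 named probe set per gene (22180 tested) and 16764 with the list means as covariates. Fits of each sex alone give no contrast between sexes. The Nr1d1 difference in females was 0.026 without female knockdown arrays 3 and 4 and ran from −0.088 to 0 in leave-one-out runs, the latter without female knockdown replicate 4. In males it was −0.081 without male control arrays 1 and 6 and ran from −0.048 to 0.041 in leave-one-out runs, above 0 without male control replicate 3 or 5 or male knockdown replicate 2, 4 or 6, and no value passed the threshold. Its average over the sexes was 0.0072 and its difference between the sexes −0.038 without female knockdown arrays 3 and 4, and that difference was −0.029 without male control arrays 1 and 6 and ran from −0.012, without female knockdown replicate 4, to 0.093 in leave-one-out runs. Slc17a7 was 0.79 higher in males with the covariates, which hold that gene's own list. The correlation of the effects between the sexes stayed within 1 SD of its main value under all 34 alternatives. That SD was the spread of the Pearson correlation over other assignments of the mice.

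With the replicate number as a block, 0 probe sets passed in every knockdown contrast and 31164 between the sexes, and every list call held. The numbers did not pair the mice: residual correlations of same-numbered arrays ran from −0.10 to 0.14, with 2 of 11 over 0.1 and 1 of 11 best with its own number.

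List values are camera adjusted p. With an estimated correlation they were 0.171 for REV-ERB targets and 0.30 for lymphocyte genes in females, 0.534 for medium spiny neuron and 0.513 for microglial genes in males, 0.266 for clock genes, 0.266 for REV-ERB targets and 0.725 for medium spiny neuron genes in the average, and 0.849 for medium spiny neuron, 0.456 for microglial, 0.456 for lymphocyte and 0.809 for interferon genes in the difference. Quantile normalization gave 0.0649 for lymphocyte genes in females, and in the difference 0.140 for medium spiny neuron, 0.140 for lymphocyte and 0.0526 for interferon genes. Array weights gave 0.0701 for clock and 0.0871 for REV-ERB genes in the average, and in the difference 0.0967 for medium spiny neuron, 0.0528 for lymphocyte and 0.0528 for interferon genes. The covariates gave 0.259 for clock and 0.259 for REV-ERB genes in the average, and turned the medium spiny neuron genes, whose own mean they hold, at 0.982 in males, 0.931 in the average and 0.948 in the difference. Without female knockdown arrays 3 and 4 the values were 0.118 for REV-ERB and 0.118 for lymphocyte genes in females, 0.0610 for clock and 0.0928 for REV-ERB genes in the average, and 0.289 for medium spiny neuron, 0.199 for lymphocyte and 0.720 for interferon genes in the difference. Without male control arrays 1 and 6, the lowest of the male controls in both lists called in males, they were 0.997 for medium spiny neuron genes, with the direction turned, and 0.107 for microglial genes in males, 0.0893 for clock, 0.0893 for REV-ERB and 0.951 for medium spiny neuron genes in the average, and 0.926 for medium spiny neuron genes, turned as well, 0.189 for microglial, 0.0596 for lymphocyte and 0.189 for interferon genes in the difference. The omission of male control arrays 1 and 6 was bound to shrink the medium spiny neuron and microglial differences, as the arrays had been chosen for low means of these lists. The alternative of 1 probe set per gene moves nothing here, as the lists used that from the start.

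Leave-one-out ranges were 0.00412 to 0.179 for REV-ERB and 0.00377 to 0.20 for lymphocyte genes in females, both lost only without female knockdown replicate 4. In the average they were 0.00668 to 0.114 for clock, 0.00660 to 0.123 for REV-ERB and 7.62e-05 to 0.121 for medium spiny neuron genes. The clock call was lost without female control 4 or 5, female knockdown 4 or 5, male control 5 or 6, or male knockdown 4 or 5, and the REV-ERB call also without male control 1 or male knockdown 1 or 2. The medium spiny neuron call was lost without female control 3 or 5, female knockdown 2 or 4, male control 1 or 6, or male knockdown 5. In the difference they were 0.000620 to 0.228 for medium spiny neuron genes (lost without female control 1 or 2, female knockdown 3 or 6, male control 1 or 6, or male knockdown 5), 0.00548 to 0.209 for lymphocyte genes (lost without female control 3 or 4, female knockdown 4 or 5, male control 1, 2 or 5, or male knockdown 2, 4, 5 or 6) and 0.00135 to 0.413 for interferon genes (lost without female control 1, female knockdown 4, male control 1 or male knockdown 5). The medium spiny neuron call in males and the microglial calls in males and in the difference stayed past the threshold in every leave-one-out run. For the calls in males, leaving out a female array could not change the difference. The medium spiny neuron difference in males fell from 0.09 to 0.05 without male control replicate 1 and to 0.06 without male control replicate 6. That in the average fell from 0.05 to 0.03 without either of them. Of the values of Nr1d1 and the other named genes, 3186 kept direction and side of the threshold and 11 changed direction, those of Nr1d1 and Slc17a7 above. Signal over background was not analysed here.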

Other observations

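The tests reported here were chosen after the values had been seen, except those of the share of cortical tissue and of neuronal activity, whose predictions were written before their results. Correlations are over 23 mice after removal of the group means, with p from 100000 permutations within groups.

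Most of the genes that varied most between mice of a group varied together with genes of cortical projection neurons. Slc17a7, the vesicular glutamate transporter of cortical neurons, had a within-group SD of 1.59 and ranged from 4.64 to 11.13, the immunoglobulin gene Igkv5-43 came next with 1.23, and Cck, Prdm8 and Neurod6 had 1.14, 1.07 and 1.02. Of the 20 most variable genes 5 belong to the cortical list, and of the other 15, 10 correlated with its mean above 0.5. Among those that did not were Igkv5-43 and Jchain (SD 0.81), both immunoglobulin genes, the antigen-presenting H2-Ab1 (SD 0.70) and Ogn, a gene of the meninges (SD 0.75).

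Activity-dependent early genes followed the cortical list. Their mean correlated with it at r = 0.88 (permutation p = 1e-05, the smallest that the permutations can give; adjusted 9.5e-05 over 19 lists) and Spearman rho = 0.85 (permutation p = 3e-05, adjusted 0.000285), at r = 0.83 without the 2 mice farthest from the median, and at 0.75 in females and 0.92 in males. Of the 21 early genes 17 correlated with it above 0.5, from 0.07 for Ier2 to 0.94 for Nr4a2. Astrocyte genes went the opposite way (r = −0.78, permutation p = 0.00073, adjusted 0.00347; rho = −0.75, permutation p = 0.00074; r = −0.71 without the 2 farthest mice), though at −0.25 in females and −0.90 in males. In all, 6 of the 19 lists passed the adjustment for r, the others being GABA and glutamate receptors (r = 0.69, rho = 0.72, permutation p = 0.00046 and 0.0004), interneurons, whose list holds Cck (0.67, rho = 0.78, both permutation p = 1e-05), the p53 response (0.64, rho = 0.71, permutation p = 0.00209 and 0.00055) and myelin (−0.63, rho = −0.52, permutation p = 0.00854 and 0.0244). Without the 2 farthest mice these r were 0.72, 0.65, 0.58 and −0.49, and the myelin value was −0.08 in females and −0.77 in males. Medium spiny neuron genes had r = −0.19 overall (permutation p = 0.510; rho = −0.28, permutation p = 0.270), made of −0.93 in females and 0.05 in males.

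A candidate explanation is a varying share of cortical tissue in the punch. A second list of 5 cortical genes had to correlate with the first in each sex. It held Mef2c, Lamp5, Dkk3, Ntng2 and Rprm, of which the striatum also expresses some. The correlation was 0.811 in females and 0.871 in males, although Lamp5 (0.02) and Rprm (0.26) did not follow. Any cause that moves cortical genes together would give this, so the test cannot decide for the tissue share. Medium spiny neuron genes fell as the cortical mean rose in females (r = −0.93) but not in males (0.05). Neuronal activity before death is another candidate. The mean pairwise correlation of the early genes fell from 0.556 to 0.245 once the cortical score was regressed out. This left covariation that the score does not carry, which other shared causes would leave as well. Both explanations remain open, and they can hold together. No biological explanation tied to a group was tested.

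Nr1d1 varied with part of the clock. Among 9 clock genes, Npas2 (r = 0.67, permutation p = 0.00418, adjusted 0.0325; rho = 0.65, permutation p = 0.0046) and Cry1 (r = −0.59, permutation p = 0.00723, adjusted 0.0325; rho = −0.65, permutation p = 0.00355) passed the adjustment. Without the 2 farthest mice r was 0.68 for Npas2 and −0.46 for Cry1, and within sexes it was 0.35 in females and 0.80 in males for Npas2 and −0.80 and −0.49 for Cry1. Dbp (r = 0.62, permutation p = 0.0213; rho = 0.46, permutation p = 0.0761) and Ciart (r = 0.56, permutation p = 0.0255; rho = 0.56, permutation p = 0.0144) had an adjusted p of 0.0573 for r, and for rho of 0.171 and 0.0433. Arntl, Nr1d2, Per3, Tef and Bhlhe41 had r between −0.26 and 0.11. Npas2 and Cry1 both belong to the REV-ERB repressed list, yet their r had opposite signs. The cortical score was not removed from these values, so a share of the covariation may come with it.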
